A study of Mus musculus with 40 samples.

How the data were processed

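Bulk RNA was measured in 8 normal livers, in 10 adjacent livers and 10 tumours of mice given DEN and CCl4, and in 9 libraries of sorted stellate cells, and single-cell RNA in 3 libraries of sorted stellate cells. Per the submitters' processing notes, the TPM values of the bulk libraries were made by the authors with bcl2fastq 2.19 and kallisto 0.44.0, and the builds named are GRCm38 and mm10. The deposited tables hold 1 TPM value per gene symbol and library in 3 tables, of normal and adjacent liver (35199 genes), of tumours (35197) and of stellate cells (35243). TPM is a share of each library corrected for transcript length, so read depth is unknown and a gene can change because others do. The single-cell UMI counts were made by the authors with Cell Ranger 5.0.1 on mm10, per the submitters' processing notes, and deposited as matrices of called cells. The annotation release is not given in the sources used here. Of the columns for stellate cells 8 belong to no labelled sample and were not used here, and 26 names that were date-like or repeated, with 0.244% of TPM, were left out.

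The comparisons, their tests, the gene lists and the rule for naming genes were fixed before the data were examined. Bulk values were tested with limma 3.58.1 in R 4.3.3 on log2(TPM + 1), with a trend of the variance over abundance, for genes with a mean of at least 1 TPM over the libraries in the fit. Tests were 2-sided, and p values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Normal livers and both adjacent groups shared a fit of 18 libraries, tumours had their own fit of 10, and stellate cells one of 9. The difference between tumour and adjacent liver was tested as an interaction over 20 libraries and the genes present in both tables, so that only differences within a table were compared, with libraries taken as independent. Errors of log2 changes are standard errors of the fit, and errors of TPM and CPM are standard deviations between libraries or mice. Scaling means that TPM was divided by the median ratio of each library to the geometric mean over libraries, and changes relative to the shift had the median log2 change of all genes subtracted.

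A total of 37 gene lists of 6 to 50 members, with 557 genes, was written beforehand from general knowledge of liver biology. Lists with at least 5 members measured were tested with limma's camera, which compares a list with all other genes, at its preset correlation between genes of 0.01 and again with an estimated one. Benjamini-Hochberg was applied over the lists. Neutrophil markers and sex-chromosome genes had fewer members measured in each comparison and were not tested. The limma test fry, which asks whether a list's genes move on balance in 1 direction, passed for 29, 27, 11, 1, 0 and 26 lists in the order of the comparisons in the report. Of the list members measured 351 of 464, 328 of 464, 27 of 464, 0 of 448, 0 of 481 and 249 of 507 entries passed over all genes, and 349, 322, 86, 18, 10 and 272 did when adjusted over the list alone.

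Genes were named by a fixed rule. In each bulk comparison these were the 8 largest rises and falls past the threshold with a mean of at least 5 TPM and no overlap between groups, predicted genes passed over. A panel followed (Yap1, Col1a1, Acta2, Timp1, Lox, Hgf, Cxcl12, Lrat, Ccn1, Ccn2, Alb, Afp and Mki67), and up to 4 members per list by adjusted p, or the 2 most abundant where none passed. Between single-cell models these were the panel, list members of largest ratio and the 8 largest ratios each way among genes with at least 200 UMIs, and at least 10 in the lower library. Up to 12 secreted factors that passed were to be named by adjusted p, to which panel members were added; 1 of them is not reported here. Genes outside the rule are said to be chosen after their values were seen.

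Single cells with at least 500 genes, at least 1000 UMIs and at most 15% mitochondrial UMIs were kept. The scrublet scores of scanpy 1.11.5 were to mark doublets at an automatic threshold, but at a common expected rate of 6% this marked 0 cells in CCl4 and CDAA and 36 in TAZ+FPC (1197, 0 and 36 at a rate per library). After this was seen, the cells of highest score were removed instead, up to a share of 0.8% per 1000 barcodes, which took 1273 cells in CCl4, 365 in TAZ+FPC and 423 in CDAA. Each library was clustered on its own by Leiden (leidenalg 0.10.2) at a resolution of 0.6 on 15 neighbours, 30 principal components and 2000 variable genes, without the secreted factors. Clusters were named from marker lists fixed beforehand, by a rule written after the marker counts were seen. A class needed at least 3 markers and 40% of its list, each in at least 10% of the cluster's cells and more than 2-fold above the other cells. A cluster stayed unnamed where another class reached 50%, and HSC-like clusters needed at least 8 of the 12 stellate markers detected. Within these, a cluster outside the cell cycle was myHSC-like or cyHSC-like with at least 3 markers of that class more than 2-fold above the other HSC-like clusters, and more of them than of the other class, with no minimum share of the list.

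UMIs of HSC-like cells were summed per mouse, given as UMIs per 1e6 (CPM) with exact Poisson intervals, and shares of cells with Clopper-Pearson intervals. List medians were set against 10000 random lists of like abundance, from genes with at least 20 UMIs, and detection was compared after cells were thinned to 2000 UMIs. The sums of myHSC-like and cyHSC-like cells were tested with edgeR 4.0.16 (quasi-likelihood, TMM, default filter), with the mouse as a block and adjustment over all 11869 genes tested.

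Each test was checked on data simulated from the same libraries. In the order of the comparisons in the report limma recovered 90, 98, 94, 80, 57 and 45% of genes changed 2-fold. With 4-fold changes these were 99, 100, 99, 99, 95 and 90%. Without simulated changes 0 genes were called, while regrouped real libraries gave up to 7128, so the simulation may not describe them. Of the calls 3.57, 3.88, 3.50, 7.25, 4.40 and 6.25% were false. For edgeR on the stellate classes recovery was 38% at 2-fold and 89% at 4-fold, with 8.63% of calls false.

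As alternatives, pseudocounts of 0.1 and 5, a filter at 5 TPM and none, median-ratio and quantile scaling, array weights, no variance trend, a 2-fold minimum and leaving out each library were run for bulk values. A fit of only the compared groups was run for adjacent liver. For single cells these were other Leiden resolutions (1.0 and 0.3), doublets kept, 5% mitochondrial UMIs, DESeq2 1.42.0, no filter, no block and each mouse left out. Of the alternatives 96 were planned and 19 were added after the data were seen.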

Results

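RNA was measured in mouse liver, in liver tumours and in sorted hepatic stellate cells, the liver cells that store vitamin A in health and make scar matrix after injury. Whole-tissue libraries came from 8 normal livers, from 10 livers of mice that carried tumours (the tissue around the tumours, called adjacent liver here) and from 10 tumours; whether these share mice is not given in the sources used here. Tumours had been induced with diethylnitrosamine (DEN, a carcinogen) at 25 mg/kg and 14 injections of carbon tetrachloride (CCl4, a toxin of hepatocytes). Adjacent livers and tumours were taken 2 days after the last CCl4 injection, as were the stellate cells of CCl4-treated mice. Of the adjacent livers 5 came from Yap floxed mice and 5 from Yap dHSC mice, in which Lrat-Cre deletes Yap1 in stellate cells, and the tumours divided in the same way. Sorted stellate cells were measured in bulk after 12 CCl4 injections (4 libraries) or 16 weeks of FPC diet (5 libraries), a diet of fructose, palmitate, cholesterol and trans-fat. Single stellate cells came from 1 mouse each after 19 CCl4 injections, after a TAZ plasmid with 2 months of FPC diet (TAZ+FPC), and after 3 months of CDAA diet, which is deficient in choline. Bulk stellate cells were sorted for vitamin A and a Lrat-Cre reporter, and single cells for the reporter alone.

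Bulk values were deposited as transcripts per 1e6 transcripts (TPM), which the authors computed with kallisto, so that read depth per library is unknown. Genes at 1 TPM or more numbered 10449 to 10948 in normal livers, 12081 to 12523 in adjacent livers of Yap floxed mice and 11631 to 12121 in adjacent livers of Yap dHSC mice. In tumours they numbered 11185 to 12176 (Yap dHSC) and 11490 to 12477 (Yap floxed), and in sorted stellate cells 13290 to 13476 after CCl4 and 12658 to 15177 on FPC diet. The single-cell files held 124533343 unique molecules (UMIs) in 12988 barcodes for CCl4, 57350639 in 6954 for TAZ+FPC and 56830502 in 7311 for CDAA. After filters and removal of likely doublets 10977, 6193 and 6814 cells were left, with medians of 9213, 8009 and 6850 UMIs per cell.

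The targeted gene, Yap1, encodes a transcriptional co-activator of growth and matrix genes. In normal liver its 8 libraries ranged from 13.5 to 20.3 TPM (mean ± SD 16.0 ± 2.32). In adjacent liver the 5 Yap floxed libraries lay at 25.9, 22.6, 23.2, 27.1 and 27.5 TPM, and the 5 Yap dHSC libraries at 19.0, 17.2, 22.6, 21.0 and 21.6 TPM. The Yap dHSC group averaged 20.3 ± 2.18 TPM against 25.2 ± 2.25 TPM in the Yap floxed group, a log2 change of -0.30 ± 0.11 that did not pass (limma adjusted p = 0.115). In tumours Yap1 stood at 29.3, 34.7, 25.7, 24.4 and 31.3 TPM in Yap dHSC mice and at 23.6, 32.3, 32.3, 29.7 and 34.3 TPM in Yap floxed mice. The loss of Yap1 within stellate cells of Yap dHSC mice is not measured by these whole-tissue libraries.

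**Figure D1:**
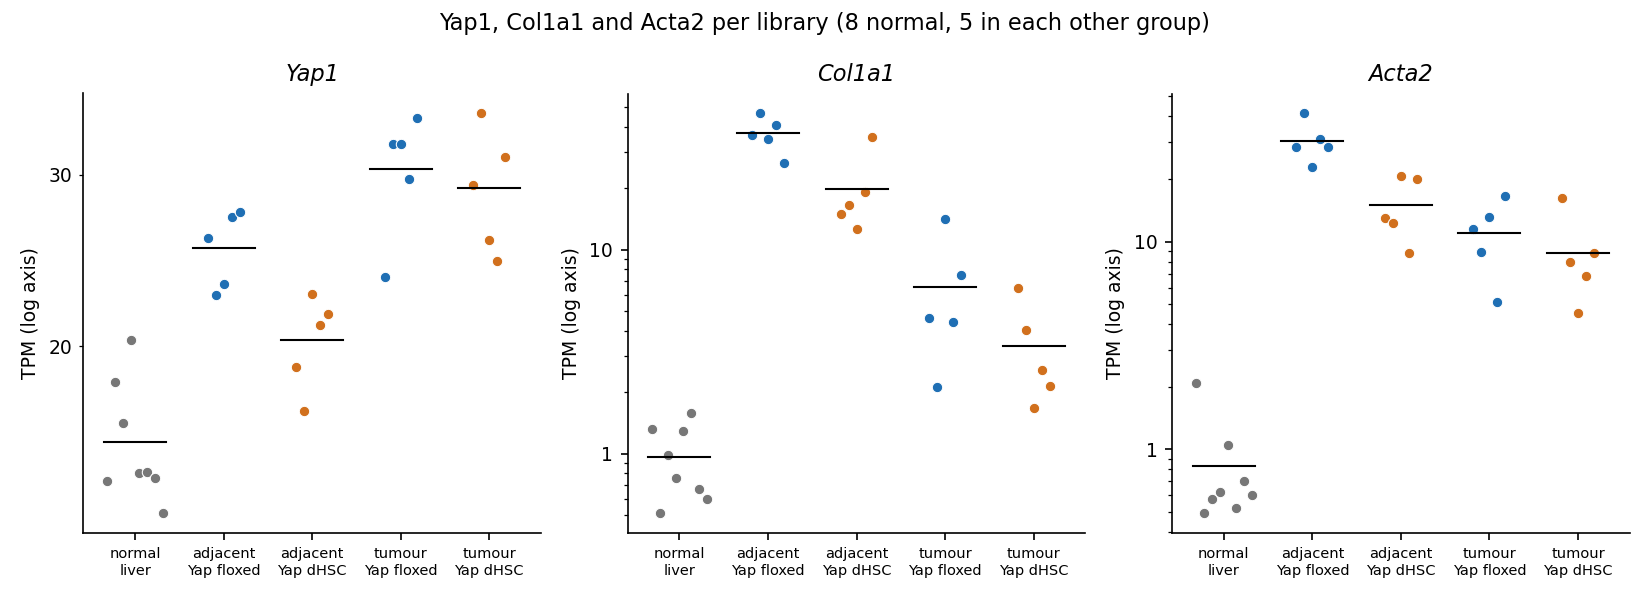
Yap1, Col1a1 and Acta2 in each whole-tissue library, in TPM on a log axis, with points for libraries and lines for group means. In adjacent liver Col1a1 averaged 37.1 TPM in Yap floxed and 19.8 TPM in Yap dHSC mice, against 0.965 TPM in normal liver, and in tumours 6.55 and 3.38 TPM.

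The adjacent liver of Yap floxed mice was compared with normal liver, which asks how liver that has gone through DEN and CCl4 differs from untreated liver. Scar and myofibroblast genes rose: Col1a1 reached 37.1 ± 7.36 TPM against 0.965 ± 0.392 TPM, Acta2, the actin of contractile myofibroblasts, 30.4 ± 6.82 TPM against 0.833 ± 0.537 TPM, and Timp1, an inhibitor of matrix proteases, 11.5 ± 5.30 TPM against 0.0936 ± 0.0955 TPM. Genes of dividing cells rose with them, among them Mki67 (9.87 against 0.253 TPM), the mitotic topoisomerase Top2a (21.7 against 0.655 TPM) and the cyclin Ccna2 (12.3 against 0.386 TPM). The iron-binding and inflammatory proteins Lcn2 (548 ± 213 TPM against 4.17 ± 0.893 TPM) and Saa2 (2624 against 35.4 TPM) and the cornified-envelope protein Sprr1a (86.0 against 0.0289 TPM) were among the largest rises. Enzymes of hepatocytes around the central vein, where CCl4 is activated, fell: Cyp2e1, which activates CCl4, went to 354 ± 123 TPM against 3383 ± 533 TPM, glutamine synthetase Glul to 40.01 ± 8.57 TPM against 312 ± 44.9 TPM and the glutamate transporter Slc1a2 to 0.795 against 29.8 TPM. Genes that male livers express more than female livers fell, including Cyp4a12a (57.3 against 202 TPM) and Ugt2b38 (2.32 against 31.8 TPM), and Cyp2a4, a female-biased gene, rose (84.5 against 0.448 TPM).

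With values as deposited 9459 of 11732 genes passed in limma, 9117 up and 342 down, and the median of all genes rose by 0.57 log2, so changes are given relative to that shift. After median-ratio scaling 5648 passed, 2868 up and 2780 down. Relative to the shift the log2 change was 6.07 ± 0.29 for Lcn2, 5.77 ± 0.24 for Sprr1a, 5.59 ± 0.44 for Saa2, 3.70 ± 0.20 for Col1a1, 3.54 ± 0.20 for Acta2, 2.83 ± 0.21 for Timp1 and 2.51 ± 0.14 for Mki67. It was 5.46 ± 0.27 for Ly6d, a membrane protein counted among liver tumour genes, 5.29 ± 0.35 for the glutathione transferase Gsta1, 4.97 ± 0.21 for the immunoglobulin chain Igha, and 4.55 ± 0.28 for the protease inhibitor Slpi. Among falls it was -4.69 ± 0.12 for Slc1a2, -4.42 ± 0.36 for the bile acid enzyme Cyp8b1, -3.88 ± 0.22 for Cyp2e1 and -3.53 ± 0.18 for Glul, and each of these calls held after scaling. The largest falls were 8 genes of the major urinary protein family (Mup15, Mup17, Mup19, Mup9, Mup7, Mup12, Mup-ps16 and Mup16), for example Mup7 at 1594 against 51256 TPM. Their sequences are nearly identical, so that reads are shared among paralogs and the level of a single one is uncertain.

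By list, all 10 myofibroblast markers measured rose (limma adjusted p = 0.0835 with an estimated correlation). So did 22 of 23 collagens and fibrillar matrix genes (0.295; 1 fell) and 15 of 16 matrix crosslinking genes (0.177), such as Col1a2, Col3a1, Mmp12 and Loxl2. All 23 cell cycle genes rose (limma adjusted p = 0.0696 with an estimated correlation). So did 12 of 15 genes of liver tumours and fetal liver (0.200), such as Afp (11.3 against 0.330 TPM), Golm1 and Akr1c18, and all 16 acute phase genes (0.117), such as Orm2 and Apcs. The falls that held with an estimated correlation were those of the male-biased liver genes (13 of 13 fell; limma adjusted p = 0.00128), the pericentral hepatocyte genes (9 of 13 fell, 1 rose; 0.00128), bile acid synthesis and transport (7 of 14 fell, 2 rose; 0.00128), the drug-metabolising cytochromes (8 of 16 fell, 2 rose; 0.00358) and the immediate early genes (8 of 15 fell, 2 rose; 0.0305). The immediate early list also differed within the normal livers: Egr1 averaged 130 TPM in libraries 1 to 5 and 19.8 TPM in libraries 6 to 8, and the clock gene Dbp 6.27 and 60.0 TPM. Hepatocyte markers divided (5 rose and 3 fell of 14; limma adjusted p = 0.149 with an estimated correlation), and after scaling 1 rose and 9 fell.

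Other cell types moved too: 13 of 16 macrophage markers rose and 1 fell (though their median also differed by 1.06 log2 between normal livers 6 to 8 and 1 to 5), with Trem2 and Gpnmb, genes of scar-associated macrophages, at 15.6 against 0.283 TPM and 14.1 against 0.0554 TPM, and all 6 cholangiocyte markers rose, with osteopontin Spp1 at 577 against 26.5 TPM. Of 15 YAP target genes 10 rose and 0 fell, and after scaling 6 rose and 5 fell; Ccn2, a matrix protein induced by YAP, reached 23.5 ± 14.9 TPM against 3.50 ± 1.23 TPM. Of 25 secreted stellate factors 19 rose (15 after scaling, with 3 falls), such as Pdgfa (11.6 against 2.80 TPM), Gas6 (31.2 against 10.8 TPM), Il33 and Nrg1. Of 13 quiescent stellate cell markers 9 rose and 1 fell (6 and 4 after scaling), with Cygb, Rgs5, Sod3 and Ednrb rising. The calls of Hgf (limma adjusted p = 0.00120; 0.0822 after scaling), Lrat (0.00332; 0.671) and Yap1 (8.77e-06; 0.890) were lost with scaling. Cxcl12 (log2 change 0.06, -0.62 after scaling), Alb (0.12, -0.56) and Ccn1 (-0.71, -1.34; 0.22 with normal livers 6 to 8 alone) did not pass as deposited and passed after scaling, as falls. Interferon-stimulated genes (15 of 17 rose), antigen presentation (12 of 13), NRF2 targets (13 of 14), p53 targets (12 of 15), hypoxia genes (9 of 12), portal fibroblast markers (5 of 5), female-biased genes (4 of 6) and lipid droplet genes (4 of 7) held rises without falls as deposited, and 0 of these lists passed the camera test with its preset correlation. After scaling camera passed upward at the preset correlation for the first 4, portal fibroblast, macrophage and cholangiocyte markers and secreted factors. Of these the secreted factors alone passed with an estimated one (limma adjusted p = 0.0370, the others 0.167 to 0.371). Endothelial markers held 6 rises of 12 as deposited and 1 rise with 4 falls after scaling, where their median changed sign.

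Metabolic lists were mixed: cholesterol synthesis (6 rose, 1 fell of 20; limma adjusted p = 0.337 with an estimated correlation), fatty acid synthesis (5 and 3 of 15; 0.149), fatty acid oxidation (6 and 0 of 14; 0.337), periportal genes (5 and 3 of 13; 0.295), retinoid storage (5 and 2 of 11; 0.295), the unfolded protein response (7 and 1 of 14; 0.337) and clock genes (7 and 2 of 13; 0.0968). After scaling these lists held 0 and 9, 0 and 5, 0 and 9, 0 and 7, 1 and 7, 3 and 3, and 3 and 4 rises and falls. In each of them, and for hepatocyte, endothelial, quiescent stellate, YAP target, lipid droplet, hypoxia and female-biased genes, the median as deposited was above 0 and the camera test, which compares a list with all other genes, pointed down. After scaling it pointed up for the quiescent stellate, YAP target, lipid droplet, hypoxia and female-biased lists, which passed neither way, and the unfolded protein response, clock and retinoid lists no longer passed (limma adjusted p = 0.335, 0.591 and 0.0745). Of the 33 lists 19 passed camera with its preset correlation and 5 with an estimated one. After scaling 9 did with an estimated one, among them myofibroblast and cell cycle genes, but not the male-biased (limma adjusted p = 0.0570) and immediate early genes (0.388). The treated and untreated mice form separate libraries without a shared control, so treatment and any handling of the groups are not separable.

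The same contrast in Yap dHSC mice asks which of these changes are present when stellate cells lack Yap1. Scar genes were again above normal liver: Col1a1 stood at 19.8 ± 9.21 TPM against 0.965 ± 0.392 TPM, Acta2 at 15.0 ± 5.20 TPM against 0.833 ± 0.537 TPM and Timp1 at 7.44 ± 2.41 TPM against 0.0936 ± 0.0955 TPM. The acute phase proteins Saa2 (3589 against 35.4 TPM) and Lcn2 (397 against 4.17 TPM) and the interferon-induced Ifi27l2b (110.4 against 2.44 TPM) were among the largest rises, with Igha, Ly6d, Gsta1, Sprr1a and the immunoglobulin segment Ighj4. Dividing-cell genes rose, for example Mki67 (7.37 against 0.253 TPM), Top2a (15.9 against 0.655 TPM) and the mitotic kinase Cdk1 (32.3 against 1.78 TPM). Pericentral Slc1a2 (0.485 against 29.8 TPM), Glul (31.5 against 312 TPM) and Cyp2e1 (460.0 against 3383 TPM) fell, as did Mup15, Mup17, Mup19, Mup9, Mup-ps16, Mup12 and Mup7, whose paralogs share reads and are uncertain one by one.

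With values as deposited 7925 of 11732 genes passed in limma, 7531 up and 394 down, around a median shift of all genes of 0.41 log2. After median-ratio scaling 4830 passed, 2507 up and 2323 down. Relative to the shift the log2 change was 6.18 ± 0.44 for Saa2, 5.69 ± 0.29 for Lcn2, 2.92 ± 0.20 for Col1a1, 2.69 ± 0.20 for Acta2, 2.50 ± 0.21 for Timp1, 2.32 ± 0.14 for Mki67, -4.78 ± 0.12 for Slc1a2 and -3.74 ± 0.18 for Glul, and these calls held after scaling. Ccn2 was 0.75 and Afp 1.92 relative to the shift, and Ccn1 fell (8.01 against 20.5 TPM; log2 change -1.10, but -0.18 with normal livers 6 to 8 alone). The call of Yap1 (limma adjusted p = 0.00558) was lost after scaling (0.226), Hgf did not pass (0.0580), and Lrat (2.74 against 3.04 TPM; log2 change -0.12, -0.49 after scaling) and Cxcl12 (-0.05, -0.54) passed only after scaling, as falls.

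Lists past camera with an estimated correlation were the cell cycle (23 of 23 rose; limma adjusted p = 0.0405) and acute phase genes (16 of 16 rose; 0.0445, with Orm2 at 637 against 17.0 TPM), and among falls the male-biased (13 of 13; 0.00502) and pericentral genes (9 of 13; 0.00502), bile acid genes (6 of 14, 2 rose; 0.00502, with Cyp8b1 at 24.3 against 184 TPM) and cytochromes (8 of 16, 2 rose; 0.0114). All 10 myofibroblast markers rose (limma adjusted p = 0.0636 with an estimated correlation), 22 of 23 collagens rose and 1 fell (0.402), and 14 of 16 crosslinking genes rose (0.311), Loxl2 among them. Rises against falls were 13 and 0 of 15 tumour and fetal genes (limma adjusted p = 0.227 with an estimated correlation), 11 and 0 of 13 antigen presentation genes (0.514), 13 and 0 of 14 NRF2 targets (0.492) and 2 and 1 of 12 endothelial markers (0.473; 1 and 7 after scaling). They were 3 and 3 of 15 fatty acid synthesis genes (limma adjusted p = 0.370 with an estimated correlation), 2 and 8 of 15 immediate early genes (0.0579), 5 and 3 of 13 clock genes (0.0776) and 4 and 2 of 11 retinoid genes (0.311). After scaling these lists held 1 and 4, 2 and 9, 3 and 5, and 1 and 6, and the medians of all but the immediate early list changed sign.

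Without passing camera as deposited, 16 of 25 secreted factors rose (14 after scaling, with 4 falls), for example Pdgfa, Gas6 and Cxcl14, and 8 of 15 YAP targets rose and 3 fell (5 and 5 after scaling). Quiescent stellate markers divided into 6 rises and 3 falls of 13, hepatocyte markers into 7 and 1 of 14, interferon-stimulated genes into 12 and 1 of 17, and periportal genes into 5 and 3 of 13. After scaling these became 4 and 5, 3 and 6, 3 and 2, and 1 and 4. Macrophage markers held 11 rises and 1 fall of 16, among them Trem2 and Cd68, and cholangiocyte markers 5 rises of 6. Rises and falls were 8 and 0 of 20 cholesterol synthesis genes, 4 and 2 of 14 fatty acid oxidation genes, 3 and 0 of 7 lipid droplet genes and 10 and 1 of 15 p53 targets. They were 6 and 1 of 14 unfolded protein response genes, 6 and 1 of 12 hypoxia genes, 5 and 0 of 5 portal fibroblast markers and 3 and 0 of 6 female-biased genes. After scaling the medians of the cholesterol synthesis (0 and 2), fatty acid oxidation (0 and 7), lipid droplet (2 and 1), unfolded protein response (2 and 2), hypoxia (4 and 4), YAP target and hepatocyte lists lay below 0. As deposited their medians lay above 0 and camera pointed down, which it also did for quiescent stellate, interferon and periportal genes. With scaling and the preset correlation camera passed upward for secreted factors, macrophage, cholangiocyte and portal fibroblast markers and downward for fatty acid oxidation, and none of these passed with an estimated one (limma adjusted p = 0.0556, 0.421, 0.296, 0.136 and 0.368). Fatty acid synthesis (0.149), clock (0.444) and retinoid genes (0.0634) no longer passed. Of 33 lists 17 passed camera with its preset correlation and 6 with an estimated one (5 after scaling, without the male-biased, pericentral and cytochrome lists at 0.0522 each).

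The adjacent livers of the Yap dHSC and Yap floxed mice were compared to ask what the deletion of Yap1 in stellate cells does to fibrotic liver. Scar genes were lower with the deletion: Col1a1 was 19.8 ± 9.21 TPM against 37.1 ± 7.36 TPM, Acta2 15.0 ± 5.20 TPM against 30.4 ± 6.82 TPM, and the basement membrane protein nidogen Nid1 10.6 ± 1.61 TPM against 24.5 ± 5.65 TPM. Lysyl oxidase Loxl2, which crosslinks collagen, was at 3.33 ± 0.754 TPM against 6.81 ± 0.903 TPM, the matrix-binding Sparc at 81.6 against 132 TPM and the collagen chaperone Serpinh1 at 22.0 against 37.0 TPM. The chromatin protein Uhrf1 (7.87 against 18.6 TPM) and Wdhd1 (3.26 against 7.81 TPM), both of replicating cells, the contractile Myl9 (7.63 against 16.6 TPM) and the interferon-induced Oasl2 (4.03 against 9.02 TPM) were also lower. The median of all genes was lower too, at -0.17 log2 as deposited. All of these calls except those of Loxl2 and Nid1 were lost after median-ratio scaling.

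As deposited 194 of 11732 genes passed in limma, 1 up and 193 down (2860 at unadjusted p under 0.05), and after scaling 2 passed, Loxl2 (log2 change -0.68, limma adjusted p = 0.0215) and Nid1 (-0.93, 0.0455). The largest falls in log2 were Sprr1a -1.28 ± 0.27, Uhrf1 -1.25 ± 0.21, Nid1 -1.13 ± 0.16, Wdhd1 -1.04 ± 0.20, Myl9 -1.03 ± 0.18, Acta2 -1.01 ± 0.22, the chloride channel regulator Clca3a1 -0.97 ± 0.20 and Oasl2 -0.96 ± 0.18. The gene that rose, the meiosis gene Rec114, named after its values were seen, was at 2.43 ± 1.28 TPM against 0.579 ± 0.723 TPM (log2 change 1.15 ± 0.29, limma adjusted p = 0.0490), with overlapping groups. Relative to the shift the changes were -0.95 for Nid1, -0.84 for Acta2, -0.77 for Col1a1 and -0.68 for Loxl2. Ccn2 (8.88 against 23.5 TPM; limma adjusted p = 0.0674), Lrat (2.74 against 5.38 TPM; 0.0538), Timp1 (0.201), Hgf (0.306), Ccn1 (0.494), Afp (0.105) and Mki67 (0.190) did not pass. Nor did Cxcl12 (log2 change -0.11, 0.08 after scaling) and Alb (0.13).

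By list, 7 of 23 collagens fell, and 17 adjusted over the list alone (median log2 change -0.64, -0.46 relative to the shift; limma adjusted p = 0.155 with an estimated correlation), such as Col5a1, Col12a1 and Col1a2. Of 10 myofibroblast markers 5 fell, and 8 adjusted over the list alone (median -0.76; limma adjusted p = 0.155 with an estimated correlation), Tpm2 among them. Of 16 crosslinking genes 5 fell, and 7 adjusted over the list alone (median -0.37; 0.155), such as Timp2 and Adamts1. Of 23 cell cycle genes 2 fell, Rrm2 and Pcna, and 11 adjusted over the list alone (limma adjusted p = 0.471 with an estimated correlation). Of 17 interferon-stimulated genes 2 fell, Oasl2 and Ifi44, and 12 adjusted over the list alone (0.155). Of 25 secreted factors 2 fell, Il33 among them, and 5 adjusted over the list alone (limma camera adjusted p = 0.223). Of 15 tumour and fetal genes 3 fell, Golm1, Epcam and Cd24a, and 5 adjusted over the list alone (limma adjusted p = 0.293 with an estimated correlation). Of 15 YAP targets 0 fell over all genes and 6 adjusted over the list alone (median -0.34; limma adjusted p = 0.322 with an estimated correlation), of 13 quiescent stellate markers 0 and 5 (median -0.42), and of 6 cholangiocyte markers 1 and 2 (0.277).

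Markers of hepatocytes did not move in the same direction: 0 of 14 passed, with a median of 0.11 and 0.28 relative to the shift, and 0 of 20 cholesterol synthesis genes passed, with medians of 0.28 and 0.46. These lists, with the cytochromes, pericentral, periportal, bile acid, fatty acid synthesis and acute phase genes, passed camera upward with its preset correlation and not with an estimated one (limma adjusted p = 0.155 for each), with 0 members past. Of 12 endothelial markers 0 fell (median -0.27) and of 16 macrophage markers 0 (median -0.46). In the remaining lists 0 members passed over all genes, and adjusted over the list alone 2 p53 targets and 1 member each of the macrophage, lipid droplet, acute phase, hypoxia, immediate early and retinoid lists did. Fatty acid oxidation, unfolded protein response, immediate early and male-biased genes had medians below 0 as deposited, medians above 0 after scaling, and camera pointed up (limma adjusted p = 0.431, 0.344, 0.344 and 0.328 with an estimated correlation). Medians below 0 with camera pointing up were also those of the portal fibroblast, lipid droplet, NRF2, clock, female-biased and retinoid lists. With scaling and the preset correlation the quiescent stellate, secreted factor and macrophage lists passed downward (limma adjusted p = 0.368, 0.103 and 0.533 with an estimated one), and the unfolded protein response, immediate early and male-biased lists (0.270, 0.719 and 0.247) no longer passed. Of 33 lists 20 passed camera with its preset correlation and 0 with an estimated one, as after scaling.

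The count depended on the libraries and settings. With a library left out the count was 2 to 799 (2, 4 and 3 without Yap dHSC replicates 6, 7 and 8, and 799 without 10). Loxl2 and Nid1 passed in each of the 3 smallest of these sets, named after their values were seen. With the 2 groups alone in the fit 0 genes passed, and with a pseudocount of 0.1 in place of 1 also 0.

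In tumours the same comparison asks whether deletion of Yap1 in stellate cells alters the tumour tissue. Collagen Col1a1 stood at 3.38 ± 1.94 TPM against 6.55 ± 4.64 TPM, Acta2 at 8.85 ± 4.40 TPM against 11.03 ± 4.31 TPM and Sparc at 73.8 ± 18.3 TPM against 95.6 ± 18.9 TPM, none of which passed. Afp, a fetal protein of liver tumours (225 against 240.4 TPM), Mki67 (6.04 against 7.32 TPM), Alb (97203 against 82857 TPM), Ccn2 (12.4 against 13.7 TPM), Ccn1 (11.7 against 10.8 TPM), Timp1 (5.00 against 8.64 TPM) and Cxcl12 (53.5 against 53.01 TPM) did not pass either. Groups did not overlap for the quiescent stellate gene Ecm1 (13.2 ± 1.68 TPM against 20.8 ± 3.77 TPM), the vitamin A enzyme Lrat (0.738 ± 0.102 TPM against 1.34 ± 0.310 TPM), the retinol carrier Rbp4 (5117 against 3820.5 TPM) and the steroid dehydrogenase Akr1c18 (564 ± 24.8 TPM against 443 ± 27.6 TPM), with an adjusted p of 0.999 for each. In limma 0 of 11960 genes passed (417 at unadjusted p under 0.05, 138 up and 279 down), and 0 passed after median-ratio scaling and in every other setting run. Groups did not overlap for 60 genes, where chance gives a share of 0.00794. The median shift of all genes was -0.04 log2.

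Adjusted over the list alone, 7 of 12 quiescent stellate cell markers were lower in Yap dHSC tumours (median log2 change -0.57; limma adjusted p = 0.138 with an estimated correlation), as were 4 of 15 fatty acid synthesis genes (median -0.48; 0.324). Adjusted over the list alone 3 of 19 collagens (median -0.50; limma adjusted p = 0.324 with an estimated correlation) and 3 of 14 cytochromes (median -0.37; 0.426) were lower, and 1 of 15 tumour and fetal genes was higher (0.351). Myofibroblast markers had a median of -0.48 (0 of 8 passed; limma adjusted p = 0.458 with an estimated correlation), crosslinking genes -0.31 (0 of 17; 0.352), NRF2 targets -0.56 (0 of 16; 0.352), lipid droplet genes -0.45 (0 of 7; 0.324) and p53 targets 0.20 (0 of 16; 0.324). YAP targets had a median of -0.02 (0 of 16 passed), secreted factors -0.10 (0 of 27), endothelial markers -0.07 (0 of 12), macrophage markers -0.17 (0 of 15) and hepatocyte markers 0.08 (0 of 14). Cell cycle genes had a median of -0.23 (0 of 23 passed; limma adjusted p = 0.721 with an estimated correlation), bile acid genes -0.41 (0 of 14; 0.481), acute phase genes -0.29 (0 of 16; 0.426) and the unfolded protein response -0.29 (0 of 14; 0.605). Hypoxia genes had -0.25 (0 of 12 passed; limma adjusted p = 0.324 with an estimated correlation), periportal genes 0.20 (0 of 13; 0.324), cholesterol synthesis 0.06 (0 of 20; 0.624) and clock genes 0.23 (0 of 13; 0.324). Of 32 lists 18 passed camera with its preset correlation, 5 up and 13 down, and 0 with an estimated one. After scaling the tumour and fetal genes (limma camera adjusted p = 0.0989), the unfolded protein response (0.0603) and clock genes (0.0538) no longer passed. For hepatocyte and retinoid genes the median was above 0 and the mean below it, and for YAP targets and fatty acid oxidation both lay below 0 and camera pointed up.

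Whether the effect of the deletion differs between tumour and adjacent liver was tested as the difference of the 2 log2 changes. Fatty acid synthesis genes had a median difference below 0, with 0 members past (median -0.61; limma adjusted p = 0.159 with an estimated correlation), with the desaturase Scd1 at a difference of -0.94 ± 0.34. Cytochromes (-0.40; 0.159), pericentral genes (-0.48; 0.168) and bile acid genes (-0.38; 0.159) had median differences below 0 as well. Targets of p53, the DNA-damage regulator, had a median difference of 0.59 (limma adjusted p = 0.209 with an estimated correlation), with Mdm2 at 0.77 ± 0.22, and genes of liver tumours and fetal liver one of 0.54 (0.442), with Akr1c18 at 1.22 ± 0.38. The differences were 0.24 ± 0.16 for Yap1, 0.71 ± 0.41 for Acta2, 0.26 ± 0.49 for Col1a1, 1.15 ± 0.69 for Ccn2 and 0.35 ± 0.26 for Lrat. None of these genes passed: in limma 0 of 12138 genes did (800 at unadjusted p under 0.05, 720 up and 80 down), around a median of all genes of 0.13 log2.

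Adjusted over the list alone, 6 of 16 p53 targets had a higher and 1 a lower effect in tumours, and 3 of 15 tumour and fetal genes a higher one. Of 33 lists 14 passed camera with its preset correlation, 2 up and 12 down, and 0 with an estimated one. For collagens the median difference was 0.07, for myofibroblast markers 0.26, for YAP targets 0.26, for secreted factors 0.15, for hepatocyte markers 0.02, for endothelial markers 0.20 and for macrophage markers 0.26, with 0 members past in each. Camera pointed down for the collagen, secreted factor and hepatocyte lists although their medians lay above 0. After scaling it pointed up for the first 2 without passing, and the medians of collagens and hepatocyte markers lay below 0. After scaling YAP targets and interferon-stimulated genes passed upward at the preset correlation and not with an estimated one (limma adjusted p = 0.491 and 0.570), and immediate early (0.358) and male-biased genes (0.0919) no longer passed. Leaving out 1 library changed the count of 0 in 3 cases, with genes named after their values were seen. Without tumour Yap dHSC replicate 2 Wdhd1 passed up and Gm12895 and Gm12896 down. Without tumour Yap floxed replicate 8 Tagln2 passed up, and without tumour Yap floxed replicate 10 Gm12895 and Gm12896 passed down.

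Sorted stellate cells of mice on FPC diet were compared with those of CCl4-treated mice, which sets a dietary model of fatty liver fibrosis beside a toxic one. Matrix genes were far lower on the diet: Col1a1 stood at 710.4 ± 201 TPM against 7229.8 ± 1609 TPM, Acta2 at 104 ± 29.99 TPM against 955 ± 476 TPM, the crosslinking enzyme Lox at 22.0 ± 6.22 TPM against 201 ± 61.3 TPM and Ltbp2 at 9.72 ± 3.65 TPM against 468 ± 95.02 TPM. Genes of dividing cells were lower, with Mki67 at 6.10 against 35.3 TPM and Cdk1 at 23.4 against 149.8 TPM. Genes of quiescent stellate cells were higher, among them the hedgehog inhibitor Hhip (79.2 ± 17.3 TPM against 13.5 ± 6.41 TPM), Ecm1 (15775 ± 3888 TPM against 3761 ± 1053 TPM), the receptor Ngfr (297 against 137 TPM) and the vitamin A enzyme Lrat (995 ± 160.3 TPM against 572 ± 195 TPM). Some growth factors fell, such as Tgfb3 (20.9 against 101 TPM), Igf1 (18.1 against 129 TPM), Gas6 (27.7 against 249 TPM) and Wnt5a (9.28 against 75.8 TPM), whereas Hgf, a mitogen of hepatocytes (877 ± 159 TPM against 792 ± 13.7 TPM), and the chemokine Cxcl12 (4292 against 3383 TPM) did not pass. Hepatocyte genes were higher on the diet, with Alb at 1434 ± 1018 TPM against 80.9 ± 72.1 TPM and Fabp1 at 388 against 9.22 TPM.

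In limma 2810 of 13931 genes passed, 773 up and 2037 down, with a median shift of all genes of -0.20 log2. After median-ratio scaling 2285 passed, 1056 up and 1229 down. Relative to the shift the log2 changes were -5.32 ± 0.31 for Ltbp2, -3.16 ± 0.29 for Col1a1, -2.86 ± 0.40 for Acta2, -2.91 ± 0.29 for Lox, -2.30 ± 0.54 for Mki67, 2.74 ± 0.28 for Hhip, 2.27 ± 0.35 for Ecm1, 1.04 ± 0.24 for Lrat and 4.44 ± 0.58 for Alb. The largest falls were the immunoglobulin genes Igkc (0.121 against 86.3 TPM) and Igha, the adhesion gene Cadm4 (0.470 against 87.5 TPM), Ltbp2, the peptidase Dpep1, the calcium binder Casq2, the elastic-fibre protein Mfap4 and the fibrinogen-like Fgl2 (1.18 against 71.0 TPM). The 8 largest rises were Mup genes of hepatocytes (Mup19, Mup14, Mup11, Mup17, Mup15, Mup20, Mup16 and Mup9), whose paralogs share reads and are uncertain one by one. Yap1 (117 against 91.3 TPM; limma adjusted p = 0.215), Timp1 (0.525), and the YAP targets listed as Cyr61 (1548 against 1868 TPM; 0.425) and Ctgf (608 against 600.0 TPM; 0.809) did not pass.

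By list, 16 of 17 myofibroblast markers fell (median log2 change -2.65; limma adjusted p = 0.107 with an estimated correlation), as did 21 of 27 collagens (median -1.55; 0.107), 9 of 22 crosslinking genes (-0.68; 0.107) such as Loxl1 and Mmp2, and 22 of 23 cell cycle genes (-2.05; 0.208). Of 15 quiescent stellate markers 9 rose and 0 fell (0.93; limma adjusted p = 0.189 with an estimated correlation), Rgs5 among them. Of 47 secreted factors 9 rose and 15 fell (11 and 16 adjusted over the list alone), and their median of 0.09 and mean of -0.31 differed in sign (limma camera adjusted p = 0.304). Of 20 YAP targets 1 rose, Nt5e, and 4 fell, such as Myof (limma camera adjusted p = 0.816), or 2 and 7 without it. Of 18 interferon-stimulated genes 8 rose, for example Ifit1 (53.7 against 17.96 TPM) and Gbp2 (limma adjusted p = 0.156 with an estimated correlation), and of 13 antigen presentation genes 3 rose, H2-Q7 among them (0.293).

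Genes of other cells moved with the groups. All 14 hepatocyte markers rose (median 4.25; limma adjusted p = 0.0778 with an estimated correlation), as did 15 of 15 cytochromes (0.0778), 6 of 12 pericentral (0.0778) and 8 of 13 periportal genes (0.107), and 9 of 14 bile acid genes with 1 fall (0.0778). Rises and falls were 9 and 2 of 16 acute phase genes (limma adjusted p = 0.177 with an estimated correlation), 6 and 1 of 11 male-biased genes (0.0778), 6 and 1 of 15 fatty acid oxidation genes (0.182) and 4 and 0 of 15 fatty acid synthesis genes (0.175). They were 3 and 0 of 7 lipid droplet genes (limma adjusted p = 0.0778 with an estimated correlation), 5 and 1 of 14 NRF2 targets (0.182) and 4 and 1 of 11 retinoid genes (0.151), lists to which hepatocytes contribute. Cidec, Cyp4a14 and Elovl3 were listed at 0 TPM in all CCl4 libraries, so no fold is given. Macrophage markers fell (7 of 16; limma adjusted p = 0.430 with an estimated correlation), with Lyz2 at 53.6 against 194 TPM, as did portal fibroblast and mesothelial markers (7 of 10; 0.0778), with Dpt at 45.6 against 718 TPM, Cd34 and Wt1, and smooth muscle markers (5 of 7, 1 rose; 0.222). Endothelial markers had a median of 1.47, with 2 of 12 past (0.213), and 1 of 5 lymphocyte markers fell.

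Of 16 p53 targets 1 rose and 3 fell, of 10 tumour and fetal genes 1 and 3, of 19 cholesterol synthesis genes 1 and 2, and of 15 immediate early genes 1 and 1. Of 12 unfolded protein response genes (limma adjusted p = 0.379 with an estimated correlation), 12 hypoxia genes and 14 clock genes 0 passed, and for the immediate early list that p was 0.330. Median and mean differed in sign for the hypoxia and lymphocyte lists, and for cholesterol synthesis and p53 targets both lay below 0 and camera pointed up. After scaling 13 secreted factors rose and 12 fell, and 3 macrophage markers fell. Of 33 lists 25 passed camera with its preset correlation and 0 with an estimated one. FPC replicate 6 was unlike its group, at a correlation across genes of 0.8075 with the mean of the others (others 0.967 to 0.975). Without it 5888 genes passed, 1397 up and 4491 down. Then 4 unfolded protein response genes rose, 5 clock genes fell and 2 hypoxia genes moved each way. Diet, its length and the interval since the last dose differ between the groups together.

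**Figure D2:**
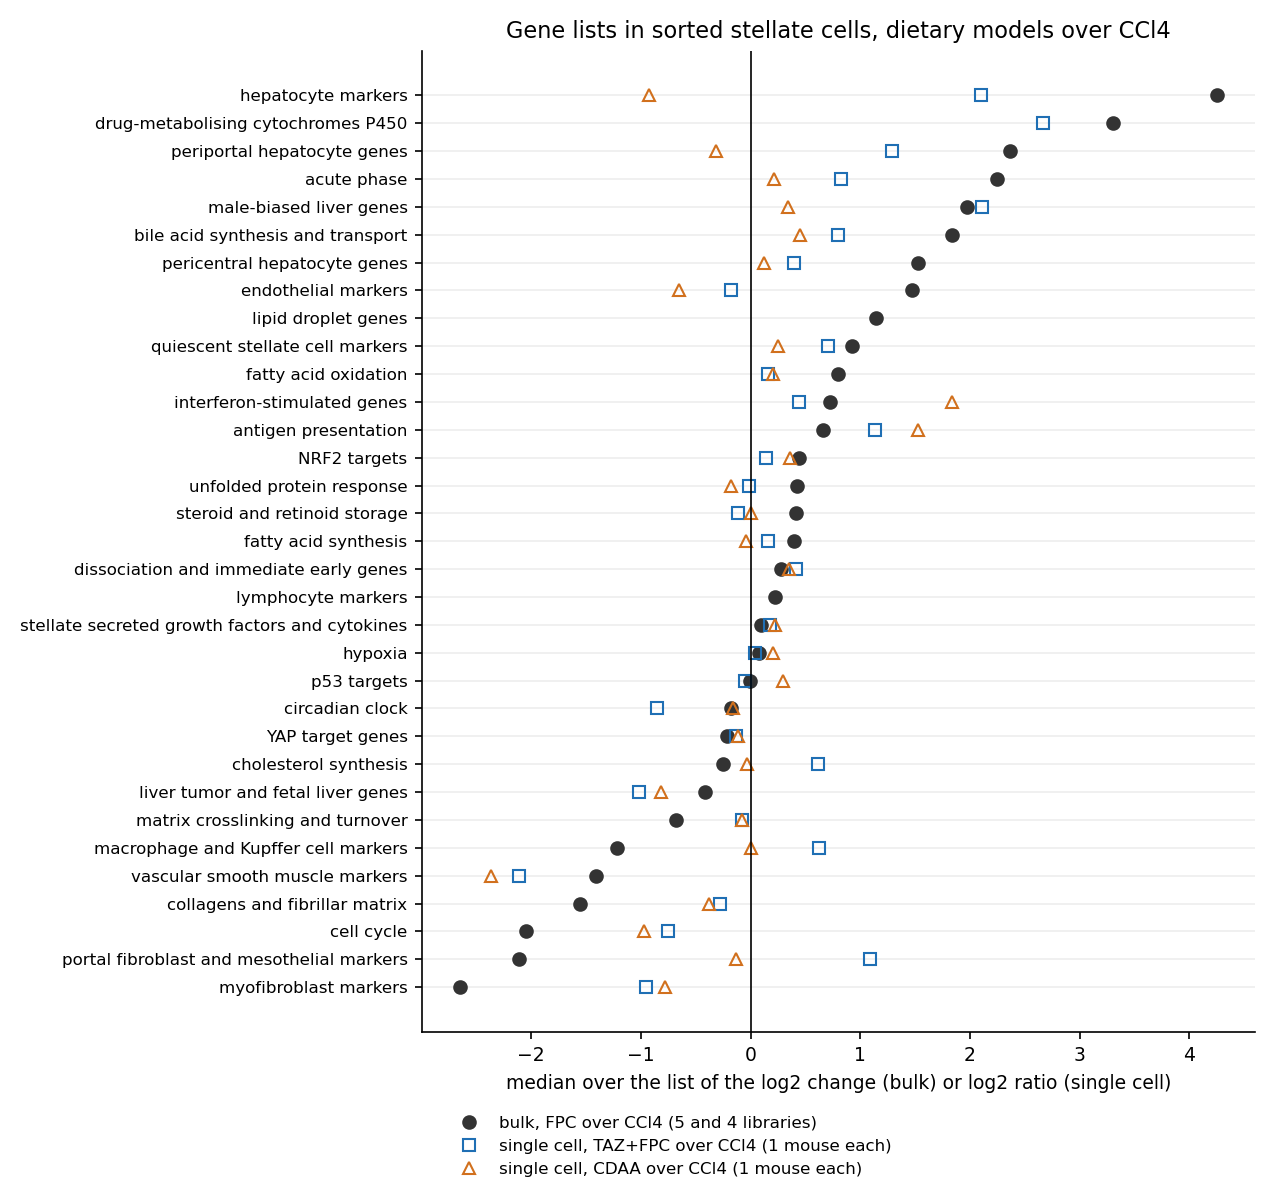
Median log2 change of gene lists in sorted stellate cells, FPC diet over CCl4 (bulk, filled points), and median log2 ratio in single cells, TAZ+FPC and CDAA over CCl4 (open points), 1 mouse per model. Myofibroblast markers had medians of -2.65, -0.95 and -0.78, and quiescent stellate markers 0.93, 0.71 and 0.25.

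Single cells show which cell classes the sorted suspensions held; cells had been sorted for the Lrat-Cre reporter, so shares describe the sort and not the liver. Stellate-like (HSC-like) cells made up 94.3% of cells in the CCl4 mouse (95% Clopper-Pearson interval 93.9 to 94.7%), 82.6% in TAZ+FPC (81.6 to 83.5%) and 93.2% in CDAA (92.5 to 93.7%), in 8, 6 and 7 clusters. Endothelial-like cells were 2.71%, 4.80% and 1.41% and macrophage-like cells 0.401%, 3.29% and 1.64%. At the settings chosen the TAZ+FPC mouse also had portal fibroblast-like (4.72%), smooth muscle-like (1.66%), lymphocyte-like (0.517%) and mesothelial-like cells (0.161%), the CCl4 mouse mesothelial-like cells (1.20%) and the CDAA mouse hepatocyte-like cells (0.338%). Unnamed clusters held 1.38%, 2.24% and 3.45%. Intervals cover counting error only, and with 1 mouse per model no test between models was run.

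Across the HSC-like cells of each mouse, matrix and contractile genes were lower in both dietary mice than in the CCl4 mouse. Col1a1 stood at 8783 UMIs per 1e6 UMIs (CPM) in CCl4, 3545 in TAZ+FPC and 3465 in CDAA, Acta2 at 1614, 329 and 495, and Lox at 226, 86.6 and 149.6 CPM. Timp1 was higher in both (367, 671 and 903 CPM). Hgf (469, 434 and 568 CPM), Cxcl12 (1613, 1359 and 2019) and Yap1 (45.5, 43.9 and 50.2) differed less, and Mki67 stood at 33.7, 14.0 and 10.5 CPM. The acute phase genes Saa3 and Lcn2 were high in the CDAA mouse alone, at 313 and 243 CPM against 3.39 and 2.79 in CCl4. In the TAZ+FPC mouse the leptin receptor Lepr (14.7 against 0.197 CPM), the calcification inhibitor Mgp (2417 against 59.6) and the antigen-presenting H2-Ab1 (17.2 against 0.413) were far above CCl4.

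The largest TAZ+FPC to CCl4 ratios were those of Lepr (74.9), Pi16 (51.9), H2-Ab1 (41.7), Mgp (40.6), Opcml, H2-Aa (36.0), Tspan11 and Cd74 (32.4). In this mouse H2-Ab1 and Cd74 stood at 1889 and 4896 CPM in macrophage-like cells, against 17.2 and 28.0 CPM in HSC-like cells, and Mgp at 5121 CPM in portal fibroblast-like cells. The lowest were those of Rian (a fold of 35.7 below), Meg3 (31.8), Rgs2 (21.5), Ccl24 (20.7), Casq2, Lama5, Camk2a and Fabp4 (16.7). For CDAA to CCl4 the largest were Saa3 (92.4), Lcn2 (87.2), Cxcl5 (34.4), Lrrc55, Chl1, Cxcl13 (19.6), Ly6a (16.8) and Chp2. The lowest were Col6a5 (a fold of 20.8 below), Snhg11, Thy1 (17.9), Cadm4 (17.8), Mest, Angpt4, Meg3 and the smooth muscle myosin Myh11 (11.9). For CDAA to TAZ+FPC the largest were Lcn2 (98.6), Saa3 (88.1), Ly6a (24.1) and the complement gene C3 (21.7), and the lowest Col6a5 (a fold of 98.0 below), Nfasc (67.8) and Lepr (42.8). In the CDAA mouse 1 HSC-like cluster of 1085 cells held 72.7% of the Saa3, 59.6% of the Lcn2 and 53.5% of the Cxcl5 UMIs of HSC-like cells.

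By list, myofibroblast markers had median log2 ratios to CCl4 of -0.95 in TAZ+FPC and -0.78 in CDAA. Like cell cycle and smooth muscle lists they lay below all 10000 random lists in each. Cell cycle genes had -0.76 and -0.97, with 545, 104 and 113 cells in cycling clusters. Quiescent stellate markers had 0.71 and 0.25, collagens -0.28 and -0.38, YAP targets -0.13 and -0.12, and secreted factors 0.18 and 0.22. Interferon-stimulated (0.44 and 1.84) and antigen presentation genes (1.14 and 1.52) were higher in both dietary mice. In TAZ+FPC macrophage markers had 0.62 and portal fibroblast markers 1.09. Hepatocyte markers had 2.10 in TAZ+FPC and -0.93 in CDAA, with Alb at 13.0, 53.2 and 6.34 CPM, levels that RNA outside cells can give. Smooth muscle markers had -2.11 and -2.37 and clock genes -0.86 and -0.16. Between the dietary mice the largest list differences, CDAA over TAZ+FPC, were of hepatocyte markers (-2.88), male-biased (-2.63), interferon-stimulated (1.20), clock (1.14) and acute phase genes (-1.08). Markers of another class over all remaining cells outnumbered stellate ones in 1, 1 and 2 HSC-like clusters with 16.4%, 31.7% and 38.5% of HSC-like cells; without these the myofibroblast medians were -1.14 and -0.45, and in TAZ+FPC macrophage markers had -0.016, portal fibroblast markers 0.43 and antigen presentation genes 1.26.

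At 2000 UMIs per cell Acta2 was detected in 68.9% of HSC-like cells in CCl4, 21.3% in TAZ+FPC and 24.7% in CDAA. In endothelial-like cells, which should lack it, the shares were 16.7%, 0.347% and 6.15%, with 111, 9 and 31 cells of lower depth left out. At 1000 UMIs, with none left out, they were 7.74%, 0% and 2.08% against 55.7%, 13.8% and 17.9% of HSC-like cells. Across genes, which are not independent replicates, the bulk log2 change of FPC over CCl4 was set beside the single-cell ratios to CCl4. Spearman correlations were 0.192 for TAZ+FPC (11196 genes) and 0.334 for CDAA (11193), or 0.315 and 0.377 without FPC library 6.

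Within each mouse secreted factors were compared between myofibroblastic (myHSC-like) cells, which express scar matrix, and cyHSC-like cells. In each mouse 1 cluster was myHSC-like, with 1234, 392 and 747 cells in CCl4, TAZ+FPC and CDAA (7, 5 and 10 of 16 markers), and 1 cyHSC-like, with 1650, 919 and 721 cells (11 of 13 markers in each). The sizes of both classes depend on the clustering, with 1689, 2446 and 3032 myHSC-like and 1356, 822 and 407 cyHSC-like cells at a Leiden resolution of 0.3. The factors were held out of clustering and markers, so cy (cytokine and growth factor expressing) is only a label. Hgf, a mitogen of hepatocytes, was higher in cyHSC-like cells (912 ± 132 CPM against 225 ± 74.2 CPM in myHSC-like cells, n = 3 mice; edgeR adjusted p = 0.00996). The vascular ligand Bmp10 (119 against 3.64 CPM), the chemokines Cxcl10 (339 against 12.6 CPM), Cxcl2 and Cxcl5 and the growth factor Bmp5 were higher in cyHSC-like cells as well. The cytokines Il6 (62.7 ± 43.8 CPM in myHSC-like against 4.07 ± 2.23 CPM) and Lif, Tgfb3 (129 against 22.2 CPM), Fgf2 and Pdgfa were higher in myHSC-like cells. Cxcl12, which attracts leukocytes, was at 2806 CPM in cyHSC-like and 613 CPM in myHSC-like cells (edgeR adjusted p = 0.0461).

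Of 45 factors measured 28 passed in edgeR with the mouse as a block, 15 higher in myHSC-like and 13 in cyHSC-like cells, and 31 adjusted over the list alone (16 and 15). Folds towards myHSC-like cells were 15.5 for Il6 (edgeR adjusted p = 0.00203), 10.2 for Lif (0.0111), 6.10 for Tgfb3 (0.00622), 3.01 for Fgf2 (0.00552) and 2.05 for Pdgfa (0.0107). Folds towards cyHSC-like cells were 34.3 for Cxcl10 (0.0115), 33.1 for Bmp10 (0.0103), 10.6 for Cxcl5 (0.00688), 5.42 for Cxcl12, 4.01 for Hgf, 3.91 for Bmp5 (0.0113) and 3.53 for Cxcl2 (0.0107). Each of these 12 factors differed in the same direction in 3 of 3 mice, although Cxcl5 had 2, 0 and 44 UMIs in the myHSC-like cells of CCl4, TAZ+FPC and CDAA. Without the CCl4 mouse 1 factor passed, Il6; without the CDAA mouse 24 and without the TAZ+FPC mouse 31 passed. With doublets kept 13 passed, and of those named Cxcl2, Cxcl5, Cxcl10 and Cxcl12 did not; the rule for doublets was changed after the data were seen. The classes were drawn from the same cells that are compared, so that the p values describe the 3 mice and do not count the choice of clusters.

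**Figure D3:**
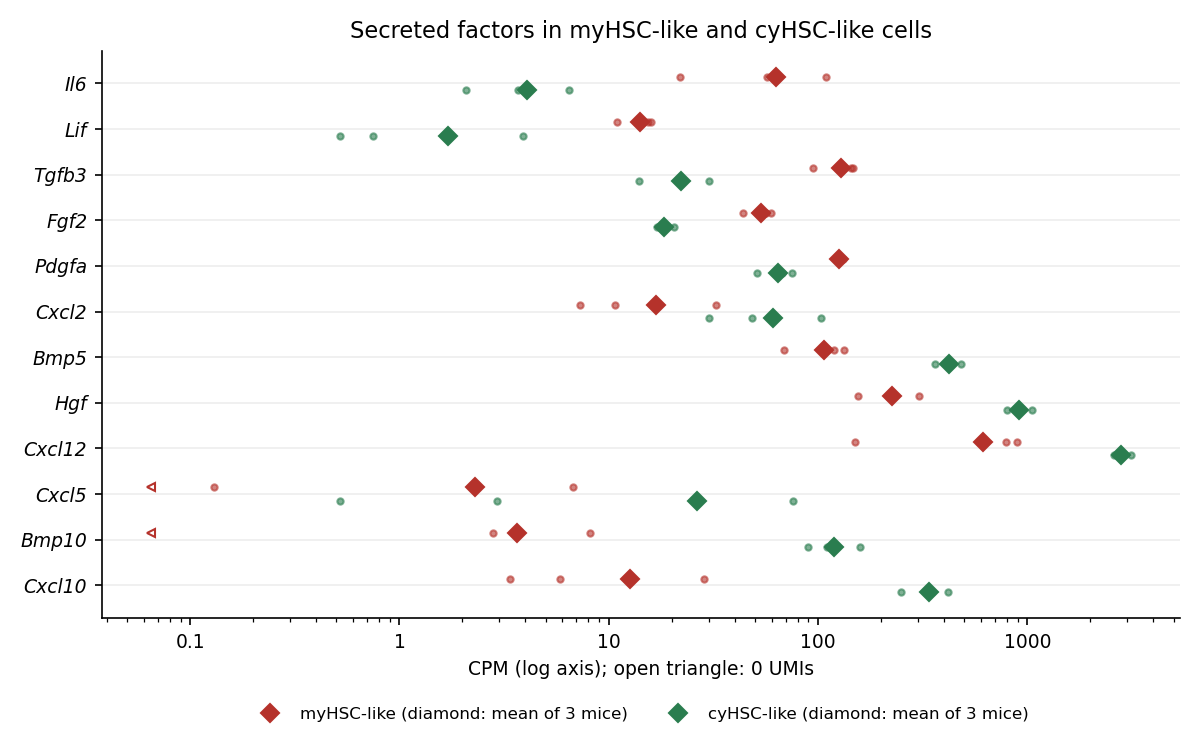
Secreted factors named above from the comparison of myHSC-like with cyHSC-like cells, as mean CPM of 3 mice per class on a log axis with a point per mouse, ordered by fold. Cxcl10 averaged 338.8 CPM in cyHSC-like and 12.6 CPM in myHSC-like cells, and Il6 4.07 and 62.7 CPM.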

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

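Chosen after results were seen were the tests of both explanations for the lower matrix genes, of a shift of all genes for the hepatocyte genes and of other cells and a few genes in FPC library 6, and all splits of the samples. Each gene named in the report was checked in each group for a library whose distance to its nearest neighbour takes up most of the group's range (Dixon's ratio above its 95% critical value), as were 2 properties of each library. Of 365 such checks 45 had a library apart. Independent normal values, unlike these, give 18.25.

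FPC replicate 6 held 15177 genes at 1 TPM or more (other FPC libraries 12658 to 13104) and the correlation of 0.8075. It stood apart with high Yap1 (166 TPM, others 98.2 to 114), Mki67 (16.9, others 1.98 to 4.45) and Myof (23.6, others 9.29 to 13.1), and with low Cxcl12 (2252 TPM, others 4558 to 4984). FPC replicate 5 was high in Mup11 (932 TPM), Mup14 (853) and Mup15 (335), and replicate 8 in Mup20 (910.2). Igha (0.702 TPM) and Igkc (0.604) were listed above 0 in replicate 8 alone among the FPC libraries. After CCl4, replicate 53 was high in Fgl2 (116 TPM, others 49.5 to 59.6), and replicate 54 low in Igkc (70.4, others 89.6 to 93.4) and high in Mup16 (0.498) and Mup9 (1.29). Mup15 was highest in replicate 55 (2.69 TPM, others 0) and Mup20 in replicate 56 (13.02).

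In adjacent liver of Yap dHSC mice, replicate 10 was high in Col1a1 (35.7 TPM, others 12.6 to 19.2), Col5a1 (4.92, others 2.42 to 2.95) and Uhrf1 (15.3, others 4.75 to 7.50), replicate 6 high in Rec114 (4.60) and replicate 8 low in Slc1a2 (0.209). In that of Yap floxed mice, replicate 1 was high in Ccn1 (18.1 TPM) and Mup12 (20.5), replicate 2 in Rec114 (1.83), and replicate 4 in Mmp12 (39.2) and Pcna (94.1), whereas replicate 3 was low in Glul (25.2, others 41.7 to 47.4). Replicate 5 of this group was high in Cd24a (10.5 TPM), Clca3a1 (16.9), Ifi44 (8.11), Il33 (4.83) and Wdhd1 (12.4). In tumours Yap floxed replicate 8 had a correlation of 0.960 with the others of its group (others 0.977 to 0.982) and was high in Ccn1 (21.2 TPM), Tagln2 (262) and Wdhd1 (2.48). Among normal livers, replicate 1 was high in Acta2 (2.09 TPM) and Saa2 (91.2), replicate 2 in Nrg1 (0.503), replicate 3 in Ighj4 (4.76, others 0), replicate 4 in Golm1 (1.64), replicate 6 in Sprr1a (0.231, others 0) and replicate 7 in Cd68 (11.6).

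The effect of the Yap deletion differed between tumour and adjacent liver for 14 lists in limma's camera test of the interaction with its preset correlation, and for 0 with an estimated one. Median differences (tumour effect minus adjacent effect, log2) were -0.61 for fatty acid synthesis, -0.48 for pericentral genes, -0.40 for cytochromes, -0.38 for bile acid genes, -0.32 for lipid droplet genes and -0.32 for NRF2 targets. They were -0.29 for quiescent stellate markers, -0.22 for cholesterol synthesis, -0.20 for male-biased genes, -0.12 for the unfolded protein response and -0.11 for acute phase genes. Above 0 were the p53 targets (0.59), the tumour and fetal genes (0.54) and the immediate early genes (0.093, where the test pointed down).

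The lower matrix genes with Yap deletion in adjacent liver were weighed first. A shift of all genes would leave no difference once the median of all genes of each library is subtracted, and the collagen score still differed by -0.37 log2 (exact permutation p = 0.0238 over 252 arrangements, 0.0635 adjusted over 6 scores). The myofibroblast score differed by -0.54 (0.0159, 0.0635 adjusted) and the hepatocyte score by 0.31 (0.0317, 0.0635 adjusted). A limit on the unadjusted p would have excluded the shift, and it was moved to the adjusted p after the values were seen because 6 scores had been computed. Loxl2 (-0.68 ± 0.099) and Nid1 (-0.93 ± 0.15) still passed after scaling, which speaks against a shift for these 2 genes, chosen by their calls. The other matrix calls ended with scaling, with a collagen median of -0.64 before and -0.45 after it beside a shift of -0.17, and the adjusted p keeps a shift open for the list. Fewer cells other than hepatocytes of every type would lower endothelial markers as well. The collagen score over the endothelial score differed by -0.31 (exact permutation p = 0.119, 0.179 adjusted), which leaves that explanation open, while the endothelial score itself differed by -0.056 (0.540). Loss of Yap1 in stellate cells, the difference the design names, may lower matrix genes, as a hypothesis that these whole-tissue libraries leave open.

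The higher hepatocyte genes in sorted stellate cells of FPC mice were weighed next. A shift of all genes is argued against, since the hepatocyte markers kept a median log2 change of 4.44 after median-ratio scaling. RNA of hepatocytes among the sorted cells would raise abundant liver genes in proportion to Alb, and over 100 such genes the gain was 1.02 times the one predicted (quartiles 0.576 and 1.28), with 100 of 100 higher. This is consistent with hepatocyte RNA making up 1.82 to 9.78% of the FPC libraries and 0.0917 to 0.578% of the CCl4 libraries, although the cells had been sorted for vitamin A and a reporter. Whether the diet itself, the biological difference, adds to this in stellate cells stays open.

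FPC library 6 was weighed last, and the design gives no group for it, so no biological explanation was tested, nor was library quality. Its ribosomal protein genes held 0.951% of TPM (others 5.92 to 6.49%). Hepatocyte RNA is argued against as the whole cause, since after subtraction of a liver profile its correlation with the others was 0.766 (others 0.957 to 0.973), as is a share taken by a few genes such as Lars2 (152365 TPM against at most 1859), since without its 10 most abundant genes it was 0.802. Cells of another type might contribute, as endothelial markers had a median deviation of 1.69 log2, but the abundant Clec4g (134 TPM), Fcgr2b (194) and Egfl7 (50.8) were not above all other FPC libraries, while Pecam1 was (341 TPM against at most 62.6). This was the highest of 4 lists of other cells, and a condition on the 3 most abundant members was added after the values were seen. The test of a few genes replaced one of transcript length, also undecided.

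Other splits of the same libraries were counted, 100 for each bulk comparison, the real one included. For adjacent against normal liver the real split gave most genes, 9459 in Yap floxed (highest other 7128) and 7925 in Yap dHSC mice (5345). So it did for FPC against CCl4 stellate cells (2810, highest other 1605). Ranking first of 100 does not exclude chance where other splits gave calls. For the adjacent groups 2 of 100 splits gave as many as the real 194, the real one and another with 878. As 16 of the other splits gave calls and the count was 2 to 799 with a library left out, the splits do not exclude chance. In tumours and in the difference between tissues (0 genes, highest other 1 and 375) all splits reach 0 by construction. This leaves chance untested. Which libraries the splits with 878 and 375 genes set apart was not examined. For the secreted factors 4 swaps of the classes within mice are too few for a share under 0.05, with 1 swap as large, the real one (28 factors, highest other 0).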

How the results depend on the processing

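Settings chosen after the data were seen were those with normal livers 6 to 8 or 1 to 5 alone, with a liver profile subtracted, with scaling and library 6 left out together, without clusters led by markers of another class, the unblocked fit of 10 libraries and an estimated correlation with scaling; the others were planned. Over all results and settings, 4864 of 5515 values kept their side of the threshold and their sign (genes), stayed within 1.5 times (counts) or inside their interval (single-cell shares and ratios). Of the others 383 lost a call or fell further, 56 gained one or rose further, 151 left their interval and 61 changed sign; the cause was not tested unless stated. Each planned setting was run.

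For adjacent Yap floxed against normal liver the 9459 genes became 5648 with median-ratio scaling, 5679 with quantile normalisation, 4320 with scaling and normal livers 6 to 8 alone, and 5963 with scaling and normal livers 1 to 5 alone. For Yap dHSC mice the 7925 became 4830, 4810 and, with scaling and normal livers 6 to 8 alone, 3141. A 2-fold minimum, which removes genes by construction, left 2291, 1343, 7 (adjacent groups) and 1676 (stellate cells). For the adjacent groups the 194 genes became 0 with a pseudocount of 0.1, 622 with one of 5, 14 with a filter at 5 TPM, 2 and 3 with the scalings, 480 with array weights, 0 with only the 2 groups fitted (limma; 2544 and 2715 genes at unadjusted p under 0.05 in these settings), and 2 to 799 with a library left out. Without replicates 1 to 10 in turn (1 to 5 Yap floxed) it was 11, 45, 332, 29, 34, 2, 4, 3, 38 and 799. The tumour count was 0 in each setting run, and the difference between tissues gave 0 to 3 with a library left out (limma; with all libraries 417 and 800 genes at unadjusted p under 0.05). It gave 3, 1 and 2 without tumour replicates 2, 8 and 10. For stellate cells the 2810 became 6165 with array weights, 5005 with scaling and 5752 with a liver profile subtracted when library 6 was left out, and 1721 to 5888 with a library left out (1773, 1721 and 1783 without CCl4 replicates 53, 54 and 56, 5888 without FPC replicate 6). With an estimated correlation 5, 6, 0, 0, 0 and 0 lists passed in place of 19, 17, 20, 18, 14 and 25, and with scaling as well 9, 5, 0, 0, 0 and 1 did, a change of the test by construction.

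The library numbers 1 to 5 occur in both normal and adjacent Yap floxed liver, and pairing by number was checked. Libraries of the same number had correlations of their deviations between -0.0840 and 0.0860, and 2 of 5 (1 and 5) matched their own number best, a hint from the data that samples share only a number. A block for the number gave 9208 genes against 9311 for the same 10 libraries without it.

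Some genes changed sign, here as log2 changes. Against normal liver in Yap floxed mice, scaling gave -0.017 for Yap1, -0.62 for Cxcl12 and -0.56 for Alb, and quantile normalisation -0.34 for Cxcl12 and -0.065 for Lrat. Array weights gave -0.015 for Cxcl12, and leaving out a library -0.0036 to 0.13 (below 0 without Yap floxed replicate 5). With normal livers 6 to 8 alone Ccn1 was 0.22, and with scaling Cxcl12 was -0.53, Lrat -0.13 and Alb -0.56. With normal livers 1 to 5 alone and scaling Yap1 was -0.12, Cxcl12 -0.68 and Alb -0.58.

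In Yap dHSC mice against normal liver Yap1 was -0.14 with scaling, -0.098 with quantile normalisation and -0.24 with scaling and normal livers 1 to 5 alone. Hgf was -0.033 with quantile normalisation and -0.056 with scaling and normal livers 6 to 8 alone. Cxcl12 was 0.016 with normal livers 6 to 8 alone and -0.097 to 0.023 with a library left out (above 0 without normal livers 3 or 4 or replicate 6), and Lrat 0.017 with normal livers 1 to 5 alone and -0.26 to 0.0052 with a library left out (above 0 without replicate 8). Between the adjacent groups Cxcl12 was 0.081 with scaling, and Alb -0.018 to 0.25 with a library left out (below 0 without Yap dHSC replicate 7). Of the sign changes against normal liver, those that passed the threshold were Cxcl12 in Yap floxed mice with each scaling, Alb there with scaling of all or of normal livers 1 to 5, and Yap1 in Yap dHSC mice with normal livers 1 to 5 scaled.

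In tumours Alb was 0 with quantile normalisation, and Yap1 was 0.023 and Timp1 0.027 with array weights. With a library left out Cxcl12 ranged from -0.066 to 0.088, Ccn1 from -0.11 to 0.40, Ccn2 from -0.24 to 0.41 and Afp from -0.42 to 0.0091, and Col1a1 in the difference between tissues from -0.011 to 0.56 (below 0 without Yap floxed tumour replicate 7). Of the tumour genes Cxcl12 was below 0 without Yap dHSC replicates 1, 2 or 5 or Yap floxed replicates 7 or 8. Ccn1 was so without 1, 2, 6 or 9, Ccn2 without 1, 2, 4, 6, 7 or 9, and Afp above 0 without 3. In stellate cells Ctgf was 0.025 with scaling, 0.24 with scaling and 0.014 with a liver profile subtracted when library 6 was left out, and -0.49 to 0.12 with a library left out (above 0 without FPC replicates 6 or 8). With scaling and without library 6 Timp1 was 0.094 and Cyr61 0.048. Alb was 0 after subtraction of the liver profile, with and without library 6, since its own level sets what is subtracted.

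HSC-like shares in CCl4 were 91.7% at a Leiden resolution of 1.0, 91.4% with doublets kept and 95.3% at 5% mitochondrial UMIs. In TAZ+FPC they were 85.5% at 1.0, 88.0% at 0.3, 81.3% with doublets kept and 84.1% at 5% mitochondrial UMIs. Portal fibroblast-like cells were 1.86% there at 1.0 and 1.87% at 0.3, and were also named in CCl4 with doublets kept (1.40%) and in CDAA at 5% mitochondrial UMIs (2.54%). Smooth muscle-like cells were also named in CCl4 at 1.0 (0.419%). Macrophage-like cells were 1.39% in TAZ+FPC at 0.3, with no lymphocyte-like or mesothelial-like cells named. The myofibroblast median over CCl4 was -1.14 in TAZ+FPC without clusters led by other markers. In CDAA it was -0.45 without such clusters, and -0.82 both as a mean of cells and without cycling clusters. Without such clusters the TAZ+FPC to CCl4 log2 ratios were 0.11 for Hgf and 0.017 for Cxcl12, and the CDAA to TAZ+FPC ones 0.52 for Col1a1 and -0.11 for Hgf. Mki67 was 0.20 in the latter without cycling clusters. Of the secreted factors 13 passed with doublets kept and 1 to 31 with a mouse left out (1 without the CCl4 mouse). Read depth of the bulk libraries is unknown, so its effect was not tested.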

Other observations

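The division of libraries and the genes below were chosen after the values were seen, and no test was made on them. Among the 8 normal livers, replicates 1 to 5 and 6 to 8 lay on opposite sides of the first principal component, which held 37.8% of the variance, and no label used here separates them. Mean levels in replicates 1 to 5 and in 6 to 8 were 7.85 and 0.817 TPM for Arntl and 27.5 and 8.89 TPM for Ccn1. Median log2 differences of replicates 6 to 8 over 1 to 5 were -1.70 for the immediate early genes, 1.06 for macrophage markers and 0.37 for quiescent stellate markers. The median absolute difference over all genes was 0.188.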
